A study of Nicotiana benthamiana with 12 samples.

How the data were processed

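Polysomal RNA was measured by sequencing in leaves of transgenic Nicotiana benthamiana, a wild relative of tobacco used as a host in plant virology. Per the labels, the plants expressed a tagged ribosomal protein (His6FLAG-RPL18) from 1 of 3 promoters, and leaves received tobacco mosaic virus (TMV, 1 mg/ml) or, as mock, water alone. The labels' protocols state that the leaves were taken 6 days after inoculation, that plants were 5 weeks old, that polysomes were pelleted and recovered with anti-FLAG beads, and that biological replicates were grown in different months. The 12 libraries form 6 groups of 2, each a promoter line by treatment.

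The authors deposited 1 table per library with the same 59814 gene models on 9668 scaffolds, whose names carry the prefix Niben101. Each table gives raw counts of exon reads and raw counts of all reads in the gene model, as deposited by the authors, both whole numbers. It also gives RPKM (reads scaled by exon length and by library total) as deposited by the authors. The submitters' processing notes name CASAVA 1.8.2. The aligner, the counting program, the treatment of reads with several matches and the use of strand are not given in the sources used here, so gene models that overlap, lie antisense to each other or have near-identical copies carry uncertain counts. RPKM was used only to recover the library total behind it and the exon length of each gene model. The total was computed here from single-exon gene models with at least 20 reads. Each exon length was then the median over libraries of the value given by the gene model's own exon reads, RPKM and that total. Where a gene model had at least 20 reads in a library, 100% of the recovered lengths were whole within 0.01 bp. The share of reads outside gene models is 1 minus all reads in gene models over that library total. That total is taken as the mapped reads of the library, which no label states. Among the models, 2674 have identifiers with a t where other identifiers have a g. They hold 0 exon reads in all 12 libraries and entered no test.

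The files do not pair the identifiers with gene names or descriptions, and no reference table was used. The 37 gene lists fixed beforehand were to be matched by name, and 0 of them matched a gene model. No list test was therefore run. Gene models are given by identifier under the rule fixed for that case: for each comparison, up to 2 that were higher and 2 that were lower with the largest fitted change. They had to have an adjusted p below 0.05, a mean of at least 2 on the log2 CPM scale over the 12 libraries, and no overlap between the libraries of the groups compared. Gene models chosen after their values were seen are named as such. The main design, the gene naming rule and most alternatives were fixed before the data were examined.

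Exon read counts were tested with edgeR 4.0.16 (R 4.3.3): filterByExpr on the 6 groups with its minimum count of 10, TMM normalization, and a robust quasi-likelihood fit with 1 mean per group over all 12 libraries, which leaves 6 residual degrees of freedom. The filter kept 38446 gene models (64.3%), and the rest held 0.0445% of exon reads. Benjamini-Hochberg adjusted p below 0.05 counted as a change, with no fold minimum. Contrasts were TMV against mock in each line and averaged over the lines, the differences of that response between lines, and each pair of lines within a treatment. CPM values are after TMM. SE is the absolute log2 fold change over the square root of the quasi-likelihood F statistic, and the 95% intervals of differences use it. Where every library of the lower group had 0 reads, the fold is a lower bound against a floor of 3 reads over the group. Otherwise the fold of a gene model with few reads is the ratio of summed counts with a 95% exact Poisson interval. Floors and intervals cover counting error only. Measures of whole libraries were compared between treatments by exact two-sided permutation of the labels within lines (216 labellings, smallest p 0.00926), adjusted over 9 measures by Benjamini-Hochberg.

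Exon reads per library ranged from 23780596 to 46207231 and did not differ detectably between TMV and mock libraries (exact permutation p = 0.407). Common biological variation was 25.7%. On simulated counts for p35S TMV against mock, with 38446 gene models in the fit, the test recovered 71.2% of 4-fold changes, 1 of 67 changes of 2-fold and 0 of 67 of 1.5-fold, with 4 false calls. For pSUC2 against p35S in mock it recovered 66.7% of 4-fold changes and 0 of 67 of 2-fold. For the difference of the infection response between pSULTR22 and p35S it recovered 9.09% of 4-fold changes. These figures hold for sparse changes; adjusted thresholds are easier to pass where many genes change. The 2 libraries of each group differed by more than counting noise (chi-square over degrees of freedom from 35.8 to 81.5), so none was taken as a duplicate. The files carry no batch, date or lane, and p-values measure the spread between plants grown separately.

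Alternatives were DESeq2 1.42.0, its size factors in edgeR, voom with limma 3.58.1, no filter on low counts, a stricter filter (at least 1 CPM in 2 libraries and 50 reads in all), a fold minimum of 2, fits of only the groups compared, the replicate number as a block, and each library left out in turn. Scaling by library size alone, all gene model reads in place of exon reads, and leaving out the 2 TMV libraries nearest to mock were added after seeing the data. Coordinates are those of the deposited tables.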

Results

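Ribosome-bound RNA was profiled from leaves in which a FLAG-tagged large-subunit ribosomal protein was expressed from 3 promoters. p35S, the cauliflower mosaic virus promoter broadly active, drove the tag in the line labelled leaf. pSUC2, named for a sucrose transporter of phloem companion cells, and pSULTR22, named for a sulfate transporter, drove it in the lines labelled leaf phloem. Each line was infected with TMV, a tobamovirus with a positive-strand RNA genome, or mock inoculated, with 2 libraries per group and 12 in all. Exon reads per library ranged from 23780596 to 46207231 over 59814 gene models, of which 38446 were tested.

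TMV infection reorganised the ribosome-bound RNA in all 3 lines. The 100 gene models most abundant in mock leaves of the other 2 lines held 31.1% ± 1.55 of exon reads in mock libraries and 2.29% ± 1.02 in TMV libraries (SD, n = 6 each, exact permutation p = 0.00926, adjusted p = 0.0139). The 10 most abundant gene models of each library held 8.41% ± 0.862 of its exon reads in mock and 2.66% ± 0.229 in TMV (SD, n = 6 each). Gene models with at least 1 exon read numbered 41630 ± 301 in mock and 43551 ± 686 in TMV (SD, n = 6 each). The share of library reads outside gene models was 8.92% ± 1.45 in mock and 14.5% ± 0.885 in TMV. The share in introns was 12.0% ± 0.911 in mock and 10.8% ± 0.596 in TMV (exact permutation p = 0.0185, adjusted p = 0.0208). The other comparisons of this paragraph had the same exact permutation p of 0.00926, the smallest the 216 labellings allow.

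**Figure D1:**
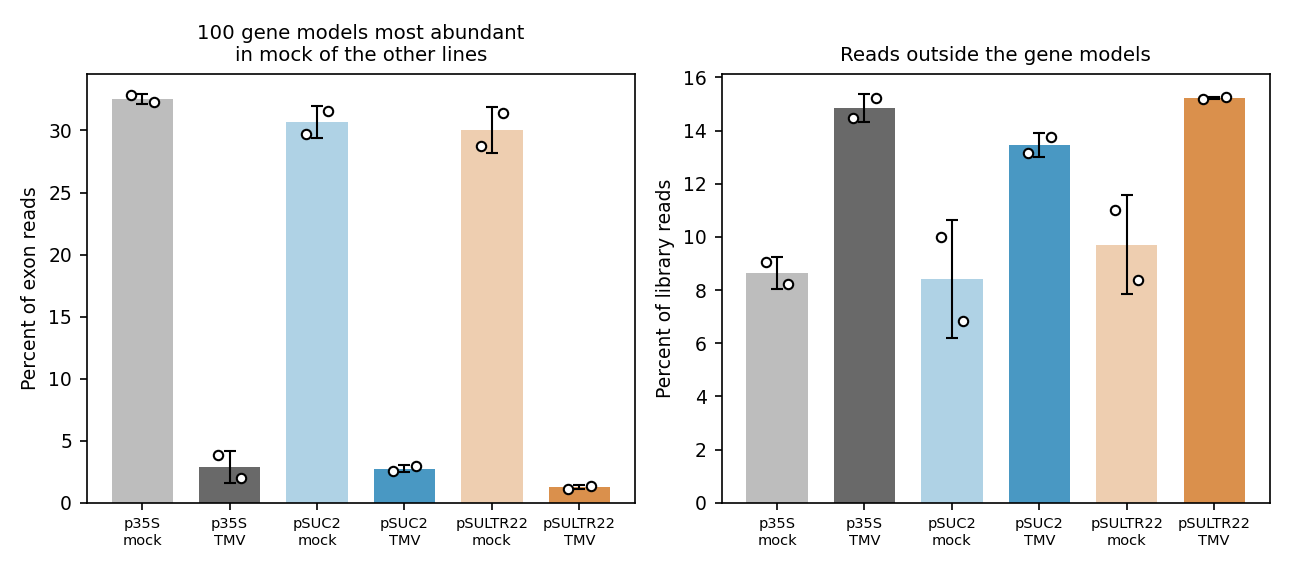
Left, percent of exon reads held by the 100 gene models most abundant in the mock libraries of the other 2 lines; right, percent of library reads outside gene models. Bars are group means, error bars the SD, circles the 2 libraries of each group. Mock libraries lie between 28.7% and 32.8% on the left and TMV libraries between 1.13% and 3.81%. On the right mock libraries lie between 6.85% and 11.02% and TMV libraries between 13.1% and 15.2%.

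Treatment separated the libraries along the first principal component, which held 87.4% of the variance. Mock libraries had scores from 208 to 225. TMV libraries had scores from -251 to -176, with p35S replicate 1 (-176) and pSUC2 replicate 2 (-185) nearest to mock. Replicates of 1 group correlated at r = 0.962 to 0.984 across gene models, and libraries of the same treatment from different lines at 0.946 to 0.985. TMV and mock libraries correlated at 0.585 to 0.731. Gene models are not independent replicates in these values.

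**Figure D2:**
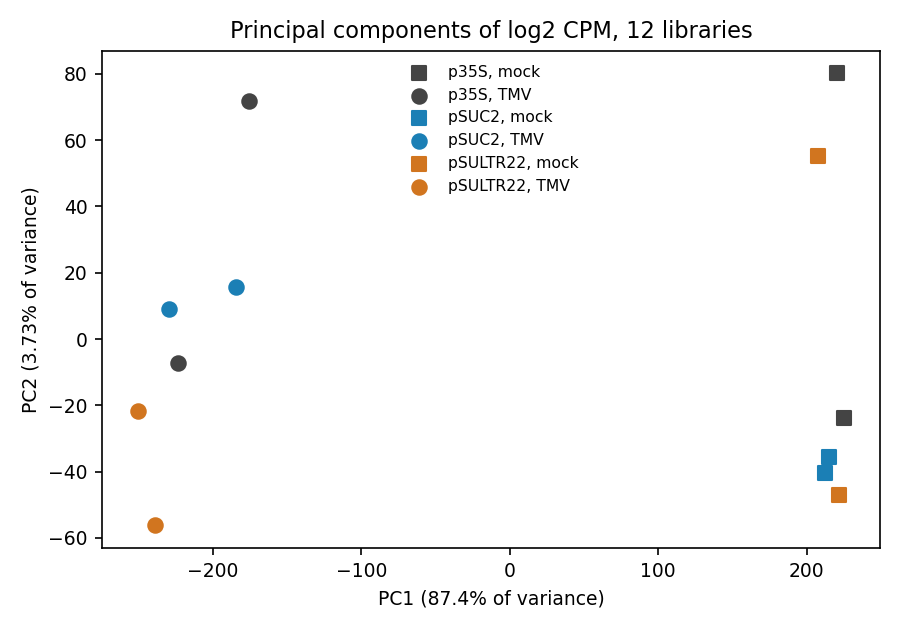
First 2 principal components of log2 CPM for the 12 libraries, with percent of variance on each axis. Squares are mock and circles TMV libraries, colours the promoter lines. The first component (87.4%) parts TMV from mock, while the scores of TMV and mock libraries overlap on the second (3.73%).

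The infection response of the p35S leaf population was read from TMV against mock in the p35S line. The gene models that dominate mock leaves fell: of the 100 most abundant in mock of the other lines, 91 fell and 0 rose, with a median log2 fold change of -4.91. Of the 1000 most abundant, 822 fell and 27 rose. Of the 100 most abundant in TMV of the other lines, 82 rose and 3 fell (median log2 fold change 4.02). In total 10916 gene models rose and 10645 fell, 56.1% of those tested, and 10888 changed at least 4-fold. Niben101Scf03628g04006 (Scf03628, 414040 to 416636, minus strand) had 49.1 ± 47.2 CPM in TMV (SD, n = 2) and 0 reads in both mock libraries, at least 899-fold higher (edgeR quasi-likelihood test, adjusted p = 3.25e-05). Its TMV libraries had 15.8 and 82.5 CPM. The single-exon model Niben101Scf00944g01001 (Scf00944, 89385 to 90989, minus strand) had 42.3 ± 16.3 CPM in TMV and 0 reads in mock, at least 694-fold higher (edgeR adjusted p = 5.75e-07). Niben101Scf00123g04002 (Scf00123, 418066 to 422220, minus strand) had 20.6 ± 2.43 CPM in mock and 0 reads in TMV, at least 476-fold lower. Niben101Scf10363g00006 (Scf10363, 33800 to 36305, plus strand) had 42.1 ± 2.82 CPM in mock and 3 reads over both TMV libraries, a ratio of 971 (95% Poisson interval 332 to 4712). Adjusted p was 4.23e-07 and 5.75e-07 for the latter 2 in edgeR.

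In the pSUC2 line, labelled leaf phloem, the same comparison gave the same pattern among abundant gene models. Of the 100 most abundant in mock of the other lines, 94 fell and 0 rose (median log2 fold change -4.59). Of the 100 most abundant in TMV of the other lines, 73 rose and 5 fell (median 3.37). In total 11397 gene models rose and 10948 fell, 58.1% of those tested, with 11310 changing at least 4-fold. Niben101Scf05301g01003 (Scf05301, 93335 to 96326, minus strand) had 45.3 ± 29.4 CPM in TMV (SD, n = 2) and 0 reads in mock, at least 969-fold higher (edgeR adjusted p = 4.82e-06). The single-exon model Niben101Scf08231g00006 (Scf08231, 50546 to 51322, plus strand) had 37.7 ± 21.4 CPM in TMV and 0 reads in mock, at least 806-fold higher (edgeR adjusted p = 4.38e-06). Niben101Scf00123g04002, also among the largest decreases in p35S, had 15.8 ± 3.63 CPM in mock and 1 read over both TMV libraries, a ratio of 1233 (95% Poisson interval 221 to 48738). Niben101Scf02513g08003 (Scf02513, 756838 to 759770, minus strand) had 500.4 ± 9.27 CPM in mock and 0.944 ± 0.212 in TMV, a log2 fold change of -9.04 (SE 0.60, edgeR adjusted p = 5.27e-07).

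The pSULTR22 line, also labelled leaf phloem, likewise had lower levels in TMV of the gene models abundant in mock. The lists of abundant gene models differ between the lines, and no test ranked the lines by this loss. Of the 100 most abundant in mock of the other lines, 99 fell and 0 rose (median log2 fold change -6.33), and of the 1000 most abundant 858 fell and 29 rose. Of the 100 most abundant in TMV of the other lines, 77 rose and 12 fell (median 3.53). In total 12184 gene models rose and 11220 fell, 60.9% of those tested, with 12451 changing at least 4-fold. Whether this response was larger than in the other lines is tested as a difference of responses, where edgeR called 0 gene models and DESeq2 230 against p35S and 295 against pSUC2, with 2206 and 2393 at an unadjusted p under 0.05 in edgeR. Niben101Scf00870g00001 (Scf00870, 78418 to 82250, minus strand) had 45.6 ± 21.4 CPM in TMV (SD, n = 2) and 0 reads in mock, at least 757-fold higher (edgeR adjusted p = 3.7e-06). Niben101Scf00072g00001 (Scf00072, 54691 to 55527, minus strand) had 25.4 ± 1.56 CPM in TMV and 0 reads in mock, at least 445-fold higher (edgeR adjusted p = 1.88e-05). Niben101Scf04543g00005 (Scf04543, 35265 to 46686, minus strand) had 25.2 ± 13.4 CPM in mock and 0 reads in TMV, at least 766-fold lower (edgeR adjusted p = 6.47e-06). Niben101Scf03969g05002 (Scf03969, 535526 to 537053, plus strand) had 248 ± 74.2 CPM in mock and 0.0893 ± 0.0526 in TMV, a log2 fold change of -11.30 (SE 0.86, edgeR adjusted p = 5.67e-07).

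Averaged over the 3 lines, TMV raised 15149 gene models and lowered 13818, 75.3% of those tested. Gene models with at most 3 exon reads over the 6 mock libraries and at least 5 CPM in every TMV library numbered 26, and 1 showed the reverse. Niben101Scf04779g01001 (Scf04779, 117389 to 119174, plus strand) had 2878 reads over the 6 TMV libraries and 0 in mock, at least 673-fold higher (edgeR adjusted p = 2.96e-07). Niben101Scf02941g00008 (Scf02941, 14229 to 15593, minus strand) had 2526 reads in TMV and 0 in mock, at least 591-fold higher (edgeR adjusted p = 2.21e-06). Niben101Scf00123g04002 had 2706 reads over the mock libraries and 2 in TMV, a ratio of 1928 (95% Poisson interval 533 to 15929, edgeR adjusted p = 6.32e-10). Niben101Scf02513g08003 fell by 9.19 on the log2 scale (SE 0.35, edgeR adjusted p = 6.33e-10).

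The gene models with the highest mean CPM in each treatment were picked after their values were seen. Niben101Scf03015g06014 (Scf03015, 591053 to 592652, plus strand), the most abundant in mock, had 35875 ± 1355 CPM in p35S mock and 1668 ± 718 in p35S TMV (SD, n = 2 each). Its log2 fold changes were -4.43 (SE 0.57) in p35S, -3.76 (SE 0.55) in pSUC2 and -5.42 (SE 0.60) in pSULTR22. Niben101Scf02041g00002 (Scf02041, 2383 to 4250, minus strand), the most abundant in TMV, had 4247 ± 1228 CPM in p35S TMV and 10.0 ± 8.73 in p35S mock. It rose in each line, with log2 fold changes of 8.72 (SE 0.92), 8.45 (SE 0.91) and 7.91 (SE 0.89) in p35S, pSUC2 and pSULTR22. All 6 changes passed the edgeR test, with adjusted p from 7.58e-06 to 9.17e-05.

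With TMM, gene models without introns and short gene models rose more often than they fell. Of the 3803 single-exon gene models, 36.5% rose and 24.1% fell in p35S, 39.0% and 22.98% in pSUC2, and 38.6% and 26.5% in pSULTR22. With scaling by library size 50.1%, 49.6% and 49.4% of them rose and 16.1%, 16.5% and 20.06% fell. Of the 34643 with introns, 27.5%, 28.6% and 30.9% rose and 28.1%, 29.1% and 29.5% fell, in the same order of lines, while under scaling by library size 46.7%, 42.3% and 46.4% rose and 17.1%, 19.4% and 20.4% fell. The gap between single-exon gene models and those with introns was thus smaller under that scaling in each line. In the shortest 20% by exon length (up to 862 bp) 31.3%, 35.1% and 36.8% rose and 20.5%, 20.01% and 22.2% fell. With scaling by library size 47.7%, 46.0% and 49.5% of these rose and 13.7%, 14.3% and 17.0% fell, against 47.1%, 43.0% and 46.7% rising among all tested gene models. In the longest 20% (2545 bp or more) 24.6%, 23.2% and 26.5% rose and 31.2%, 33.6% and 32.0% fell, and this balance flips under scaling by library size, where 46.0%, 38.5% and 44.2% rose and 17.0%, 20.6% and 19.97% fell. That scaling moves all gene models alike (17.0%, 19.2% and 20.4% of all tested fell), and the longest 20% still rose less often than all tested. The rank correlation of log2 fold change with exon length across gene models was -0.0920, -0.128 and -0.105.

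All of these directions are relative to TMM scaling, whose factors ran from 1.15 to 1.36 in TMV and from 0.698 to 0.902 in mock libraries. Scaling by library size alone shifted the median log2 fold change by 0.75 in p35S, 0.60 in pSUC2, 0.65 in pSULTR22 and 0.67 in the average. With that scaling 73.4%, 69.2%, 69.6% and 69.8% of the changed gene models rose, against 50.6%, 51.0%, 52.1% and 52.3% with TMM.

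Whether the same gene models responded in the 3 lines was asked from the overlap of calls. Gene models that rose in all 3 lines numbered 9086 and those that fell in all 3 numbered 9046, while 8 rose in 1 line and fell in another. With scaling by library size the shared rises were 14677 and the shared falls 5797. For p35S and pSUC2, 9679 gene models rose in both against 3236 for independent lists, and 9585 fell in both against 3031. For p35S and pSULTR22 the shared rises were 9868 (3459 for independent lists) and the shared falls 9634 (3107). For pSUC2 and pSULTR22 they were 9981 (3612) and 9623 (3195). The log2 fold changes correlated across gene models at r = 0.951 for p35S with pSUC2, 0.943 for p35S with pSULTR22 and 0.941 for pSUC2 with pSULTR22. The lines share no library, so no control is common to these comparisons. No marker of a cell type could be checked, so the overlap does not show that distinct populations responded alike.

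**Figure D3:**
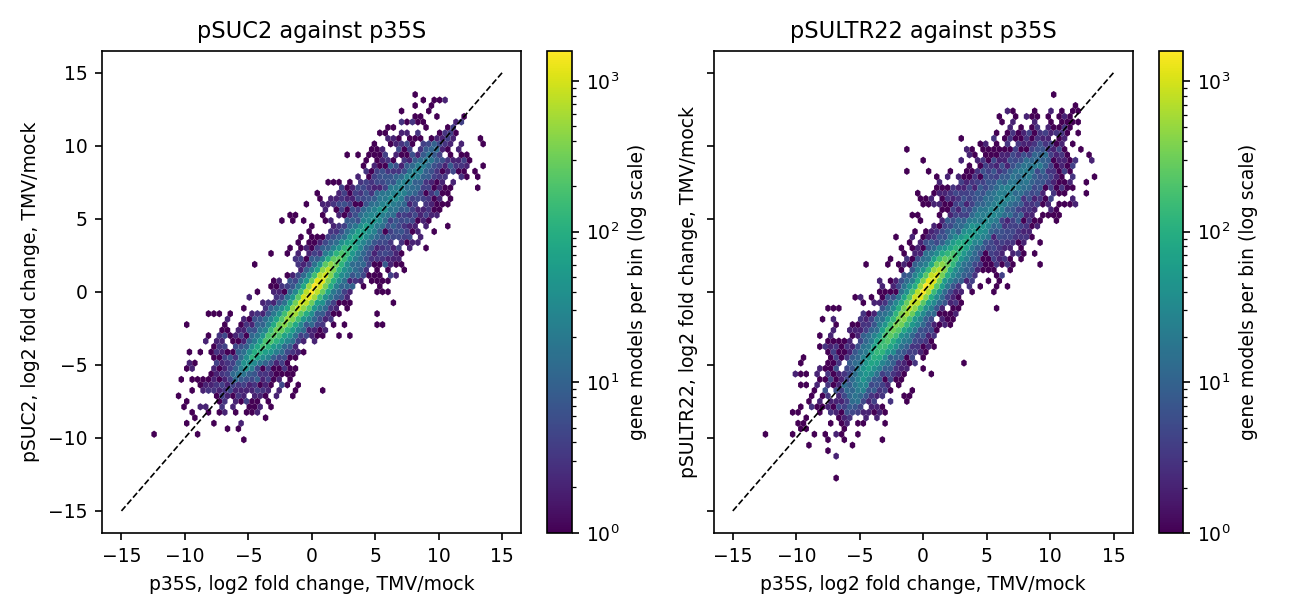
Fitted log2 fold change, TMV over mock, of each tested gene model in p35S (horizontal) against pSUC2 (left) and pSULTR22 (right); colour is the number of gene models per bin on a log scale and the dashed line marks equal change. The points follow that line, with r = 0.951 and 0.943. Fitted values of gene models with no reads in a group depend on the prior count.

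Gene models whose infection response differed between lines were sought with interaction contrasts, and edgeR called 0 in each of the 3 pairs. For pSUC2 against p35S 868 gene models had an unadjusted p under 0.05, for pSULTR22 against p35S 2206 and for pSULTR22 against pSUC2 2393, with 1922 due by chance. DESeq2 called 6, 230 and 295, and voom with limma 0 in each. Of the DESeq2 calls, 227 of 230 and 289 of 295 had a more negative log2 fold change in pSULTR22, a sign that covers deeper falls and smaller rises alike. In these 2 comparisons DESeq2 gave no adjusted p for 29070 and 28324 gene models, so the calls come from the remainder. Its median log2 difference was -0.0777 and -0.100, against -0.00175 and -0.0293 in the main edgeR fit. In edgeR 8 gene models passed for pSULTR22 against p35S without pSULTR22 mock replicate 1, and 2 for pSUC2 against p35S without p35S mock replicate 1. The median 95% interval reached 1.08 on the log2 scale to either side, and 16.7% to 19.3% of gene models had intervals within 2-fold. On simulated counts for pSULTR22 against p35S the test recovered 6 of 66 differences of 4-fold and 0 of 67 of 2-fold, so most differences of either size were not detectable.

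In mock leaves, few gene models passed the edgeR test between lines. Niben101Scf06501g02006 (Scf06501, 343889 to 346216, plus strand) stood out in pSUC2, with 27.5 ± 14.9 CPM against 0.673 ± 0.103 in p35S and 0.403 ± 0.123 in pSULTR22 (SD, n = 2). Its log2 difference was 5.35 from p35S (SE 0.47, edgeR adjusted p = 0.00293) and -6.09 for pSULTR22 against pSUC2 (SE 0.50, edgeR adjusted p = 0.00127). With 1 library left out, these log2 differences ran from 4.65 to 5.82 and from -6.56 to -5.39. The first call was lost without p35S mock replicate 2 and the second without pSULTR22 mock replicate 2. Niben101Scf12540g00015, chosen after its values were seen because its mean is below the naming limit, had 0.485 CPM in pSUC2, 5.80 ± 0.461 in p35S and 5.71 ± 0.736 in pSULTR22 (edgeR adjusted p = 0.0125 and 0.0133). It lies on Scf12540 from 145 to 3749, plus strand. The other 2 gene models called between pSUC2 and p35S were Niben101Scf08329g00002, higher in pSUC2 (4.101 ± 0.316 CPM against 2 reads in p35S, edgeR adjusted p = 0.0259), and Niben101Scf01789g04010, lower in pSUC2 (2 reads against 50 in p35S, a ratio of 31.5 with a 95% Poisson interval of 8.27 to 267, edgeR adjusted p = 0.0410). They lie on Scf08329 from 194825 to 195926 and on Scf01789 from 380504 to 402141, both on the plus strand. The call of Niben101Scf01789g04010 was lost under several settings, among them without p35S mock replicate 2, without either pSUC2 mock library, in a fit of these 2 groups alone and with voom and limma. Niben101Scf08329g00002 was also chosen after its values were seen.

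The full counts in mock were 4 for pSUC2 against p35S (2 higher, 2 lower), 2 for pSULTR22 against pSUC2 (1 higher, 1 lower) and 0 for pSULTR22 against p35S. At an unadjusted p under 0.05 edgeR had 4460, 1406 and 1819 gene models in that order, with 1922 due by chance, and DESeq2 called 171, 17 and 22. The number for pSUC2 against p35S lay above the chance number, and on simulated counts that comparison recovered 0 of 67 changes of 2-fold. Leaving out 1 library moved the first count to 10 (without p35S mock replicate 1), 0 (without p35S mock replicate 2) or 1 (without either pSUC2 mock library). The second count went to 1 without either pSUC2 mock library and to 0 without pSULTR22 mock replicate 2. The 95% interval of the difference lay within 2-fold for 38.5% to 47.8% of gene models. These include gene models with 0 reads in both groups, whose fitted difference and SE were 0 and which carry no information on likeness.

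In TMV-infected leaves, edgeR called 284 gene models between pSULTR22 and p35S. Of these, 235 were lower and 49 higher in pSULTR22. The fit with the replicate number as a block called 14, with neither Niben101Scf06751g00002 nor Niben101Scf09186g00006 among them. Niben101Scf06751g00002 (Scf06751, 118559 to 125438, plus strand) had 387 ± 41.5 CPM in pSULTR22 and 16.9 ± 3.45 in p35S, and also 558 ± 252 in pSUC2 (SD, n = 2). Its log2 difference between pSULTR22 and p35S was 4.52 (SE 0.70, edgeR adjusted p = 0.0258). Niben101Scf09186g00006 (Scf09186, 131993 to 146236, plus strand) had 48.4 ± 8.71 CPM against 3.01 ± 0.665 (log2 difference 4.01, SE 0.69, edgeR adjusted p = 0.0278). Niben101Scf11585g00003 (Scf11585, 69452 to 76325, minus strand) was lower, at 3.28 ± 0.174 CPM against 68.5 ± 48.6 (log2 difference -4.39, SE 0.55, edgeR adjusted p = 0.0189). Niben101Scf00578g00008 (Scf00578, 1462 to 4491, plus strand) had 3 reads in pSULTR22 and 68 in p35S, a ratio of 30.8 (95% Poisson interval 10.1 to 153). Without p35S TMV replicate 1 the count was 2, without p35S TMV replicate 2 it was 833, and without either pSULTR22 TMV library it was 0. With both p35S TMV replicate 1 and pSUC2 TMV replicate 2 left out it was 8, and DESeq2 called 1330.

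Between pSUC2 and p35S in TMV leaves, 6 gene models were higher and 3 lower in pSUC2. Niben101Scf06501g02006 was again higher in pSUC2, at 16.8 ± 0.163 CPM against 1.42 ± 0.480 (log2 difference 3.54, SE 0.42, edgeR adjusted p = 0.0183). Its call was lost without any 1 of the 4 libraries compared, at log2 differences from 3.23 to 3.93. Niben101Scf01731g10001 (Scf01731, 1103716 to 1115764, plus strand) had 32.9 ± 17.1 CPM in pSUC2 and 3.495 ± 1.32 in p35S (log2 difference 3.23, SE 0.41, edgeR adjusted p = 0.0239). Niben101Scf11585g00003 was lower, at 1.70 ± 0.558 CPM in pSUC2 (log2 difference -5.33, SE 0.59, edgeR adjusted p = 0.0149). Niben101Scf10608g02009 (Scf10608, 187801 to 192099, minus strand) was lower, at 26.6 ± 5.16 CPM against 170 ± 15.0 (log2 difference -2.68, SE 0.34, edgeR adjusted p = 0.0239). The count of 9 fell to 1 without either p35S TMV library or without pSUC2 TMV replicate 2, and to 0 without pSUC2 TMV replicate 1 or in a fit of these 2 groups alone. Leaving out both p35S TMV replicate 1 and pSUC2 TMV replicate 2 also gave 0, and DESeq2 called 43.

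Between the 2 lines labelled leaf phloem in TMV leaves, 15 gene models were higher and 60 lower in pSULTR22 than in pSUC2. With the replicate number as a block only 1 was called, Niben101Scf06501g02006. Niben101Scf10608g02009 was higher in pSULTR22, at 156 ± 1.82 CPM (log2 difference 2.55, SE 0.34, edgeR adjusted p = 0.0341). Niben101Scf03987g00011 (Scf03987, 3159 to 22109, plus strand) was higher, at 3.70 ± 0.885 CPM against 0.563 ± 0.198 (log2 difference 2.70, SE 0.42, edgeR adjusted p = 0.0361). Niben101Scf06501g02006 was lower in pSULTR22, at 1.13 ± 0.389 CPM (log2 difference -3.86, SE 0.42, edgeR adjusted p = 0.0317). Niben101Scf01785g10010 (Scf01785, 972788 to 992789, minus strand) was lower, at 0.374 ± 0.161 CPM against 5.07 ± 0.540 (log2 difference -3.71, SE 0.61, edgeR adjusted p = 0.0447). Without any 1 of the 4 libraries compared the count was 0, while a fit of these 2 groups alone gave 988 and DESeq2 837.

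**Figure D4:**
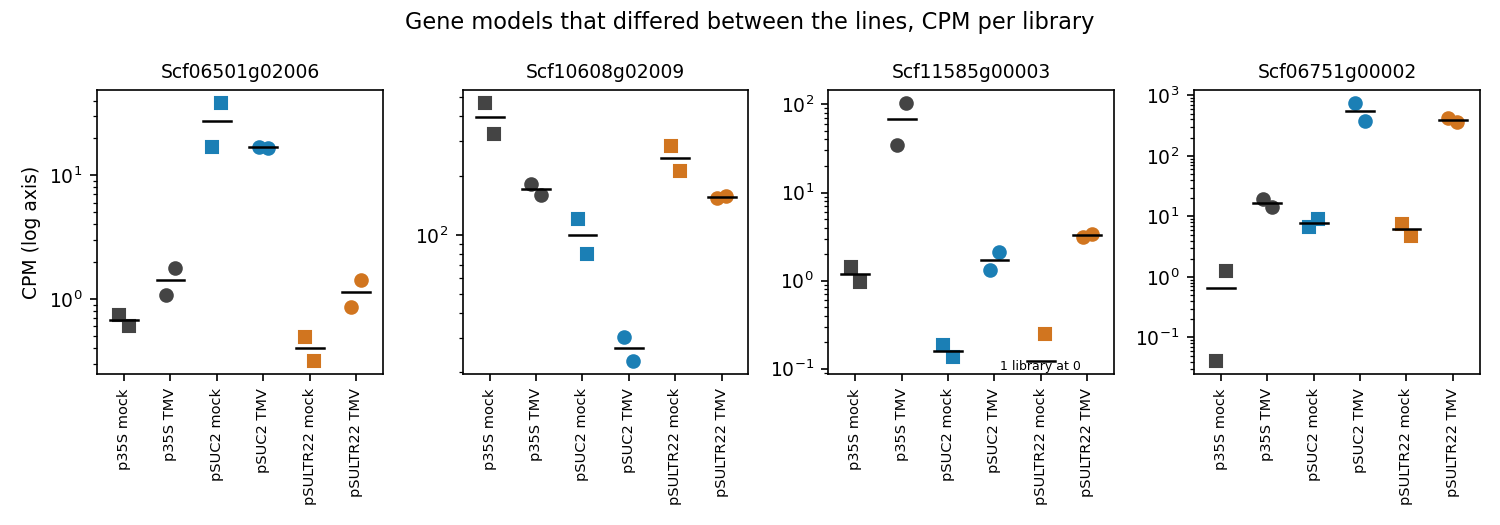
CPM on a log axis of 4 gene models that differed between lines, in the 2 libraries of each group (squares mock, circles TMV) with the group mean as a line. Scf06501g02006 has 16.6 to 38.0 CPM in the 4 pSUC2 libraries and at most 1.76 in the other 8. The library at 0 is pSULTR22 mock replicate 1 for Scf11585g00003, which a log axis cannot show.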

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

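Both results here were singled out after the data were seen. The share of library reads outside the gene models, which no comparison of gene models uses, was 14.5% in TMV libraries and 8.92% in mock libraries, above mock in 6 of 6 TMV libraries (exact permutation p = 0.00926, the smallest possible, adjusted p = 0.0139). For Niben101Scf06501g02006 the mean CPM in TMV differed from mock by -10.7 in pSUC2 and by 0.73 in pSULTR22, and was 1.42 against 0.673 in p35S, with no overlap between treatments in any of the 3 lines. By edgeR, the log2 fold changes were -0.71 in pSUC2 (adjusted p = 0.114), 1.09 in p35S (adjusted p = 0.0641) and 1.51 in pSULTR22 (adjusted p = 0.0194), so only the last passed. The separation in pSUC2 is narrow, since the lower mock library had 16.93 CPM and the higher TMV library 16.88. The difference of responses did not pass the edgeR test (pSUC2 against p35S log2 difference -1.81, adjusted p = 1.00, pSULTR22 against pSUC2 2.23, adjusted p = 0.516). No group holds 4 or more libraries, so single libraries were not tested as standing apart from their group.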

How the results depend on the processing

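The tests chosen after seeing the data were scaling by library size, all gene model reads and leaving out the 2 TMV libraries nearest to mock. The 4 counts of gene models changed by TMV stayed within 1.5 times under every alternative run: 18100 to 24640 in p35S, 17726 to 23908 in pSUC2, 19086 to 25808 in pSULTR22 and 20931 to 30902 in the average. The 24 infection changes of gene models given by identifier kept direction and call in 396 of 396 values. These gene models were picked from the same counts for large called changes or high abundance. That outcome was therefore likely beforehand and does not speak for the other calls. Of the 100 most abundant mock gene models, 90 to 93 fell in p35S, 92 to 97 in pSUC2 and 97 to 99 in pSULTR22. Rises shared by all lines numbered 14677 and shared falls 5797 with library-size scaling.

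Counts of differences between lines did not hold, and unless named the cause was not tested. In the order pSUC2 against p35S, pSULTR22 against p35S, pSULTR22 against pSUC2, DESeq2 gave 171, 22 and 17 in mock, 43, 1330 and 837 in TMV, and 6, 230 and 295 for the infection response (adjusted p not given for 29070 and 28324 gene models in the last 2). No low-count filter gave 15 and 1 for the first 2 pairs in mock, 15, 626 and 359 in TMV, and 3, 5 and 10 for the response. For pSULTR22 against pSUC2 in TMV, DESeq2's size factors gave 132, library-size scaling 169, voom with limma 237 and a fit of only the groups compared 988, which also gave 9 for the response of that pair. That fit gave 0 for pSUC2 against p35S in TMV and voom with limma 14. Voom with limma gave 1 for pSULTR22 against pSUC2 in mock. With the 2 TMV libraries nearest to mock left out, the TMV counts were 0, 8 and 10, where fewer samples were in the fit. With 1 library left out, a lone sample is assumed to vary like the other groups. The range was then 0 to 10 for pSUC2 against p35S in mock, 0 to 3 for pSULTR22 against pSUC2 in mock, 0 to 1, 0 to 833 and 0 to 0 in TMV, and 0 to 2, 0 to 8 and 0 to 0 for the response. The named line differences lost their call in 71 of 222 values, 47 of them with 1 library left out, and 0 turned direction.

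Whether replicate numbers shared across groups pair the libraries is not settled, and the main fit did not pair them. The deviations of same-numbered libraries correlated at -0.395 to 0.474 (median -0.0099) over 15 pairs of groups, with 2 above 0.1. These pairs lie within and across treatments, so the range cannot exclude pairing within a treatment. Mock TMM factors were higher in replicate 1 than 2: 0.802 and 0.698 (p35S), 0.854 and 0.804 (pSUC2), 0.902 and 0.723 (pSULTR22). Shares of library reads in introns and outside gene models were higher in replicate 1 in each line in mock, and lower in each line in TMV. Exon shares, which complete the same total, went the other way in both treatments. Exon reads per library were fewer in replicate 1 in each line in mock. In TMV neither they nor the TMM factors shared an order. Such shared orders leave pairing within a treatment open. The fit with the replicate number as a block called 14 gene models for pSULTR22 against p35S in TMV and 1 for pSULTR22 against pSUC2 in TMV, 3 for pSUC2 against p35S in mock, Niben101Scf01789g04010 not among them, and 28472 in the average. The alternatives for gene lists were not run, since no list could be matched. Gene models with too few reads for the test held 0.0445% of exon reads.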

Other observations

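The evenness, intron and neighbour tests below were chosen only after the data were seen. Reads were spread over more gene models after infection: 50% of exon reads came from 473 ± 100.0 gene models in mock libraries and from 2393 ± 207 in TMV libraries (SD, n = 6 each, exact permutation p = 0.00926, the smallest possible). By group the numbers were 394 ± 25.5 in p35S mock, 513 ± 63.6 in pSUC2 mock and 512 ± 163 in pSULTR22 mock (SD, n = 2), against 2354 ± 159, 2404 ± 423 and 2423 ± 64.3 in TMV.

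Introns behaved differently per library and per gene model. Intron reads made up a smaller share of TMV than of mock libraries (10.8% and 12.0%), while the median share of a gene model's own reads that fell in introns was 8.93% in TMV and 6.93% in mock, over 25024 gene models with at least 200 exon reads in each treatment. In 1615 of them every TMV library lay above every mock library and in 268 every one lay below, where chance gives 0.108% (27.1 gene models) each if all 12 libraries are exchangeable and at most 0.463% (116 gene models) if they are exchangeable within lines. The gene models share the libraries, so they are not independent. Of the 1615, 676 rose and 619 fell in exon reads.

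Line differences measured in mock and in TMV libraries share no library. For pSUC2 minus p35S they correlated across gene models at r = 0.368 (rho 0.418, exact permutation p = 0.0222, the smallest the 90 labellings allow, adjusted p = 0.200 over 9 correlations). For pSULTR22 minus p35S r was 0.205 (exact permutation p = 0.422) and for pSULTR22 minus pSUC2 0.00538 (exact permutation p = 0.978). The mock difference of pSUC2 minus p35S correlated at r = 0.310 (exact permutation p = 0.178) with the TMV difference of pSULTR22 minus p35S, so the first value is not shown to be particular to its pair of lines. The gene model Niben101Scf12540g00015 was low in pSUC2 in TMV as well, at 0.579 ± 0.192 CPM against 5.54 ± 0.0398 in p35S and 3.09 ± 1.16 in pSULTR22 (SD, n = 2).

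The change of 28967 gene models with TMV was weighed against 2 technical explanations. Among 100 splits of the 4 libraries within each line, 1, the real one, gave as many, and the highest other gave 16493. That is the smallest share 100 splits can give, so chance is argued against but not excluded. Most other splits mix TMV and mock libraries in a group, which widens the spread in the fit. Their counts therefore do not show what chance alone would give. A few abundant genes taking most of the counts would shift all other gene models by 1 common factor. The median log2 fold change moved by 0.67 between TMM and scaling by library size. In the average 5589 gene models rose and 6034 fell at least 4-fold with TMM. These values argue against this explanation for changes of at least 4-fold, while smaller changes stay undecided. Removing 1793 abundant gene models, which held 61.0% of exon reads in mock and 37.3% in TMV, left 99.6% of the 27267 calls among the rest. TMM already limits the weight of abundant gene models, before and after the removal, so most calls were likely to stay. With scaling by library size alone 69.8% of the changed gene models rose, against 52.3% with TMM. The design names a response to infection, and 9086 gene models moved up and 9046 down in all 3 lines. Other differences between the treatments were not weighed, and the files carry no batch, date or lane.

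The 284 gene models that differed between pSULTR22 and p35S in TMV were weighed against 2 explanations. Of the 267 that also changed with infection in pSUC2, which shares no library with this comparison, 251 (94.0%) differed in the direction infection moved them, so pSULTR22 libraries may stand further along a common response. Their mean distance along the response of the other lines was 1.06 ± 0.0231, against 0.944 ± 0.0744 in p35S (SD, n = 2). Each line was measured against the mean response of the other 2, so these values use different yardsticks. A wider response in pSULTR22 would raise its own value and lower that of p35S, so the gap is partly built in. The covariate below carries the same limit. With each library's distance as a covariate 72.8% of the median difference was left, from 2.21 (median SE 0.39) to 1.61 (median SE 0.49) on the log2 scale. The bootstrap interval of 70.4% to 75.5% resampled gene models, which share the same libraries, so it leaves out the spread between libraries. Of the 284 calls 3 held as the difference shrank and its error grew, which leaves this explanation open in part. A lasting difference between the populations stays open too: 84.5% had the same direction in mock, against 59.99% of all tested gene models, but 12 of 90 labellings of the mock libraries gave as much (one-sided exact permutation p = 0.133).

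Neighbouring gene models on 1 strand changed together. Adjacent pairs within 1 kb on the same strand had a rank correlation of average log2 fold changes of 0.619 (bootstrap interval over scaffolds 0.563 to 0.661, 1029 pairs). It was 0.222 (0.167 to 0.275, 1709 pairs) at 1 to 5 kb, 0.179 (0.144 to 0.210, 3580 pairs) at 5 to 20 kb and -0.00168 for shuffled pairs. The high value within 1 kb is the one weighed here. It could come from 1 transcript being counted in 2 neighbouring gene models, or from tandem copies sharing reads, and these could not be separated without sequences. Other causes limited to pairs on 1 strand, shared regulation among them, were not tested, so the value is not shown to come from counting. Regulation of whole regions whatever the strand is argued against as the cause of the high value within 1 kb, since pairs on opposite strands at that distance had a rank correlation of 0.0531 (-0.00629 to 0.109, 1347 pairs). Pairs on opposite strands had 0.0780 (0.0363 to 0.128) at 1 to 5 kb and 0.0923 (0.0497 to 0.138) at 5 to 20 kb, so a weak shared change of regions stays open. Counts of changed gene models may therefore include some transcripts more than once.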
